A study of Mus musculus with 6 samples.

How the data were processed

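Total RNA of RAW264.7 mouse macrophages was measured by bulk RNA sequencing, in 3 libraries with RANKL and 3 with RANKL plus etelcalcetide. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table per library with an FPKM value (fragments scaled by exon length and by the library total) for each of 55536 Ensembl gene IDs. Per the submitters' processing notes, the tools were CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0 and DESeq2 1.22.1, with no role or order given. The same notes name the human build GRCh38, but all 55536 IDs matched the mouse annotation GENCODE M21, and the 2 sets of IDs were the same, so coordinates (1-based) and gene classes were taken from M21 on GRCm38. Whether libraries were made by poly(A) selection or by rRNA removal is not given in the sources used here, which limits what values of histone, rRNA and nuclear noncoding genes mean. Library strandedness is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and the share of exon length in an overlap is stated for some genes.

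FPKM multiplied by the merged exon length of the annotation gave whole reads for 100% of values in every library, within a tolerance of 0.01 reads, and the value of 1 read gave the same total as the sum of those reads. Recovered totals were 15259425, 15877596 and 14530043 reads for RANKL replicates 1 to 3, and 15425298, 13742913 and 16264432 for etelcalcetide replicates 1 to 3. At that depth 1 read on a 1 kb gene was worth 0.0615 to 0.0728 FPKM. Within each group the replicate pairs differed beyond sampling noise (chi-square per gene 5.38 to 29.0), so no library was counted as a copy of another. This chi-square is a mean over genes, which a single abundant gene can raise. The rRNA gene CT010467.1 took 0.647%, 2.53% and 0.323% of reads in etelcalcetide replicates 1, 2 and 3, so the upper values are not typical of a gene. Such differences do not show separate cultures. Counting intervals and floors cover counting error only.

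The planned test was a count model, but the deposited unit was FPKM, and the comparison was made on these values with limma 3.58.1 in R 4.3.3; edgeR was not used. FPKM values were divided by trimmed-mean-of-M-values factors computed from the recovered reads (trimming 30% of M and 5% of A values), a pseudocount of 0.1 FPKM was added, and log2 values were fitted with group as the only term and a mean-dependent prior variance. Genes were tested when at least 3 libraries had 0.5 FPKM and 10 reads, which left 11120 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. Printed FPKM means and SDs are the deposited values, before division by the scaling factors. For small differences their direction can therefore depart from that of the tested fold change. Where a group had 1 to 3 reads over its libraries, the ratio of depth-adjusted reads is given with its 95% exact conditional interval, and at 0 reads the floor was 3 reads over the group. Annotation handling used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

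The steps were tested on simulated reads for the same genes and depths, in which 200 genes were changed. Of 98 tested 2-fold genes 95.9% were recovered, and of 98 tested 1.5-fold genes 62.2%, among 10942 tested genes, with 4.91% false calls. The spread between simulated replicates was preset, the same for all genes and not estimated from these libraries. The rates in the real data may therefore differ. Of 200 simulated lists without a change, 3.5% had a camera p under 0.05. The simulated genes were drawn independently, so this says nothing of lists whose members vary together.

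A set of 34 gene lists was fixed before the data were examined, as were the grouping, the rule for named genes, the threshold of adjusted p and the alternatives other than those said to be added. The FPKM minimum and the pseudocount were set once the unit was known, and the minimum of 10 reads was added after a first look at the results; the FPKM minimum alone gave 5774 changed genes. The 28 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists; 16 passed, and 0 passed with an estimated correlation. Members were also counted over all genes tested and adjusted over the list alone. Named genes were Casr; 12 osteoclast genes whatever their value; the 6 rising and 6 falling genes with the largest fold change among changed genes with a mean of at least 5 CPM and no overlap between groups; and up to 4 members with the smallest adjusted p of each list described. Genes named outside that rule are said to be so where they appear, and 1 gene that the rule names is not reported here.

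Single measures per library were compared by two-sided exact permutation tests. Alternatives covered the scaling, filters, pseudocount, voom on recovered reads, a replicate block, the labelled day, each library left out in turn, a size threshold and other list tests. The main comparison had no block, because the shared replicate numbers go only with the conflicting day labels and no label says that they mark a shared culture.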

Results

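Bulk RNA sequencing was analysed for 6 libraries of RAW264.7, an immortalised mouse macrophage line that turns towards osteoclasts, the bone-resorbing cells, when it is given the cytokine RANKL. All 6 libraries came from cells given RANKL at 50 ng/mL, and for 3 of them the cells also received 4 µM etelcalcetide, a peptide drug that activates the calcium-sensing receptor. No library without RANKL was analysed here, so every value compares RANKL plus etelcalcetide (n = 3) with RANKL alone (n = 3). The series design gives 5 days of exposure for all samples, whereas the sample labels give 5, 6 and 7 days for replicates 1, 2 and 3 of both groups, and the true durations stay open. No label says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The deposited FPKM values corresponded to 15259425, 15877596 and 14530043 gene-assigned reads in RANKL replicates 1, 2 and 3, and to 15425298, 13742913 and 16264432 in etelcalcetide replicates 1, 2 and 3.

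The comparison asked how the transcriptome of RANKL-treated cells differed when etelcalcetide was present. Genes of bone resorption were among those that fell most: Ctsk, the collagen-degrading protease cathepsin K, went from 94.5 ± 23.1 to 0.191 ± 0.0570 FPKM (mean ± SD, n = 3 per group), and Atp6v0d2, an osteoclast subunit of the proton pump, from 31.8 ± 3.70 to 0.390 ± 0.0812 FPKM. Among genes that rose, Ccl22, a chemokine that attracts T cells, went from 2.28 ± 0.486 to 66.3 ± 3.38 FPKM, and Irf7, a transcription factor of the interferon response, from 4.76 ± 0.702 to 34.7 ± 1.85 FPKM. Several genes of osteoclast fusion and matrix degradation did not pass the test, among them Dcstamp and Mmp9. Casr, the calcium-sensing receptor itself (ENSMUSG00000051980, chromosome 16, 36493696 to 36562141), had 0 reads in all 6 libraries; a floor of 3 reads corresponds to between 0.0391 and 0.0463 FPKM per library, covering counting error only.

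Across the transcriptome, 5894 of 11120 tested genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 2896 higher and 2998 lower with etelcalcetide. With library totals alone in place of the scaling factors, 5830 genes changed, 3558 higher and 2272 lower, so the balance of directions rested on the scaling. Most changes were small: 456 genes were higher and 325 lower by at least 2-fold, and 87 and 124 by at least 4-fold. Each gene named below as higher or lower had all 3 treated values on that side of all 3 RANKL values. The values of the 2 groups did not overlap for 6804 genes (61.2%, where chance gives 10% for a single gene). This count, like the sides of named genes, used values before division by the scaling factors. Those factors were 0.967 to 0.978 in the RANKL libraries and 1.01 to 1.04 in the treated libraries. A shift shared by many genes could therefore separate the groups by itself, and the excess over 10% is no measure of gene-specific change. The first principal component, which separated the groups, held 82.4% of the variance, and log2 values correlated across genes at 0.989 to 0.993 within groups and 0.937 to 0.948 between them.

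The 6 genes that rose most under the fixed rule were Ccr7, Ccl22, Treml4, Marcks, Il1b and Nr4a3. Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes (chromosome 11, 99144196 to 99155077), rose from 0.136 ± 0.106 to 16.1 ± 3.25 FPKM, a log2 fold change of 6.13 (SE 0.316, limma adjusted p = 1.35e-06). Ccl22 (chromosome 8, 94745590 to 94751699) rose by 4.75 (SE 0.139, limma adjusted p = 9.30e-08), and Il1b, which encodes the inflammatory cytokine interleukin 1 beta (chromosome 2, 129364570 to 129371139), by 4.10 on the same scale. Treml4, a receptor of myeloid cells, went from 0.278 ± 0.251 to 8.30 ± 0.548 FPKM, and Nr4a3, an inducible nuclear receptor, from 0.0878 ± 0.00974 to 2.73 ± 0.399 FPKM. Marcks, a membrane-bound actin regulator, had 2 reads over the RANKL group and 455 over the treated group, a depth-adjusted ratio of 229 with a 95% exact counting interval of 62.9 to 1894.

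Ctsk, Rab15, Prss35, Atp6v0d2 and Vegfc were among the 6 genes that fell most under the same rule. Ctsk (chromosome 3, 95499256 to 95509362) had a log2 fold change of -8.40 (SE 0.200, limma adjusted p = 2.93e-08) and Atp6v0d2 (chromosome 4, 19876841 to 19922605) one of -6.10 (SE 0.139, limma adjusted p = 2.30e-08). Rab15, a small GTPase of endosome traffic, went from 2430 reads over the RANKL group to 2, a ratio of 1209 (95% exact counting interval 334 to 9987). Prss35, a serine protease family member, went from 1803 reads to 1, a ratio of 1794 (322 to 70888). Vegfc, a growth factor of lymphatic vessels, went from 661 reads to 1, a ratio of 658 (118 to 26013).

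Of 37 tested genes of the osteoclast list, 3 rose, 23 fell and 11 did not pass. Adjusted over the list alone, 3 rose and 25 fell. Of its 40 members, 14 also stand in other lists. Among these are Atp6v0d2 in the V-ATPase list, Src in the fusion and podosome list and Nfatc1 in the calcium list. The median log2 fold change was -0.36. Setting Oscar at its bound could not move that median, because Oscar already lay below it. The list passed limma's camera (adjusted p = 2.64e-06) but not with an estimated correlation (adjusted p = 0.509 with an estimated correlation). Acp5, the tartrate-resistant acid phosphatase used as the histological osteoclast marker (chromosome 9, 22126727 to 22135711), fell from 115 ± 22.1 to 3.93 ± 0.709 FPKM, with 6.75% of its exon length shared with an antisense gene. Slc9b2, a sodium and proton exchanger, fell from 6.92 ± 1.05 to 0.0436 ± 0.0238 FPKM. Oscar, an immunoreceptor that co-stimulates osteoclast formation, had 310 reads over the RANKL group and 0 over the treated group, at least 103-fold lower against a floor of 3 reads over the group. Nfatc1, the transcription factor that drives osteoclast genes (chromosome 18, 80606205 to 80713071), fell from 52.8 ± 6.46 to 22.1 ± 1.15 FPKM (log2 fold change -1.33, SE 0.0880, limma adjusted p = 5.91e-06). Ocstamp, a fusion protein, fell from 5.92 ± 0.716 to 2.03 ± 0.248 FPKM, and Tnfrsf11a, the receptor of RANKL, from 26.4 ± 1.48 to 21.7 ± 0.718 FPKM (limma adjusted p = 0.00143).

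Other osteoclast genes did not pass the test. Dcstamp, which is needed for cell fusion, stood at 20.7 ± 3.09 and 21.7 ± 0.819 FPKM in the RANKL and treated groups (limma adjusted p = 0.995). Mmp9, a gelatin-degrading protease, stood at 158 ± 21.7 and 163 ± 8.04 FPKM before scaling (log2 fold change -0.032 after scaling, limma adjusted p = 0.803). Itgb3, the beta chain of the osteoclast integrin, stood at 0.904 ± 0.221 and 1.10 ± 0.0756 FPKM, and Fos, a transcription factor upstream of Nfatc1, at 17.4 ± 1.61 and 19.2 ± 1.85 FPKM (limma adjusted p = 0.402 and 0.610). Calcr, the calcitonin receptor, had 4, 1 and 3 reads in RANKL replicates 1, 2 and 3 and 0 in each treated library, too few to test.

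**Figure D1:**
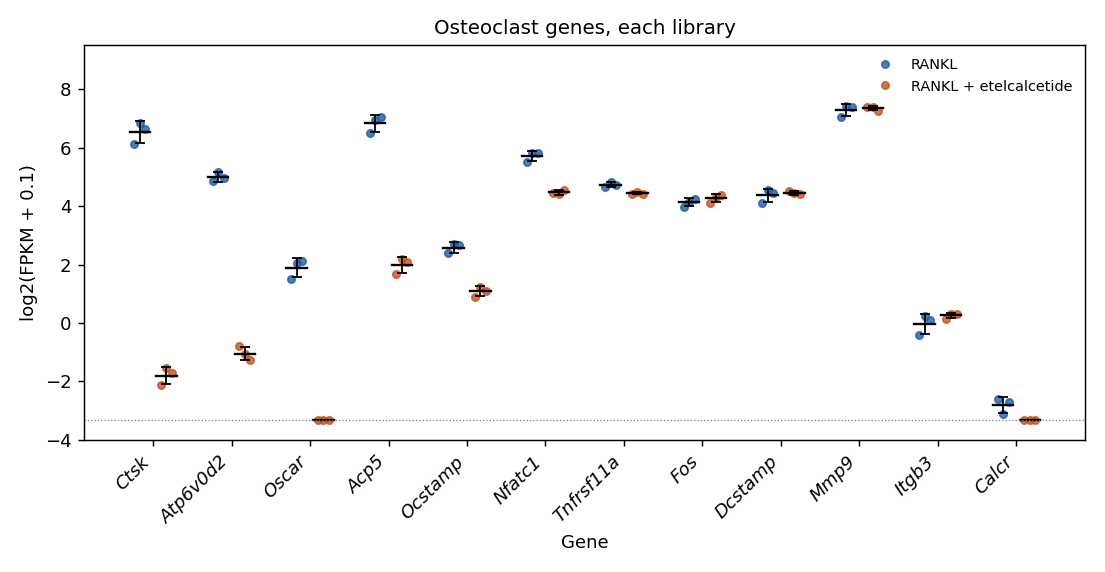
The 12 osteoclast genes of the fixed rule, with log2(FPKM + 0.1) on the vertical axis. Points are libraries (blue, RANKL; orange, RANKL plus etelcalcetide), black bars are the mean and SD of the 3 log values, and the dotted line marks 0 FPKM; Ctsk lies near 94.5 and 0.191 FPKM in the RANKL and treated groups, while the points of Dcstamp and Mmp9 lie side by side.

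The proton pump that acidifies lysosomes and the resorption space moved with the osteoclast genes only in part. Of 18 tested V-ATPase genes, 5 rose and 9 fell, and 5 rose and 10 fell adjusted over the list alone (median -0.21). Atp6v1a, a catalytic subunit, fell from 84.1 ± 2.38 to 34.2 ± 1.18 FPKM, and Atp6ap2 fell from 75.4 ± 3.15 to 36.2 ± 2.17 FPKM. The list passed limma's camera (adjusted p = 0.0367), failed without RANKL replicate 3 (adjusted p = 0.155; leave-one-out range 0.0103 to 0.155), and had an adjusted p = 0.610 with an estimated correlation. Of 33 lysosomal genes, 18 rose and 5 fell, the same numbers as when adjusted over the list alone (median 0.17, limma camera adjusted p = 0.00511, adjusted p = 0.545 with an estimated correlation). Ctsh, cathepsin H, rose from 0.156 ± 0.00393 to 3.31 ± 0.363 FPKM and Man2b1, lysosomal alpha-mannosidase, from 15.2 ± 0.878 to 37.2 ± 1.99 FPKM. Of 32 genes of cell fusion and podosomes, 12 rose and 6 fell, also when adjusted over the list alone, and the list did not pass (median 0.12, mean -0.0022, limma camera adjusted p = 0.193). Src, a kinase needed for bone resorption, fell from 8.27 ± 1.3 to 2.17 ± 0.324 FPKM, while Cd44, a hyaluronan receptor, rose from 33.9 ± 3.65 to 60.9 ± 0.708 FPKM.

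Genes that restrain osteoclast formation rose in most cases. Of 17 tested, 12 rose and 2 fell, also when adjusted over the list alone (median 0.69, limma camera adjusted p = 0.000432, adjusted p = 0.163 with an estimated correlation). Id3, an inhibitor of DNA binding by helix-loop-helix factors (chromosome 4, 136143497 to 136145755), rose from 4.70 ± 0.526 to 40.9 ± 2.20 FPKM, and Dusp1, a phosphatase of MAP kinases, from 1.8 ± 0.365 to 8.62 ± 0.723 FPKM. Of the 18 members, 8 also stand in other lists, 4 of them among the immediate-early genes. The immediate-early list, genes that respond fast to growth factor and stress signals, had 18 of 28 tested members higher and 8 lower, also when adjusted over the list alone (median 0.98, limma camera adjusted p = 0.00163, adjusted p = 0.509 with an estimated correlation). Egr1, a zinc finger factor (chromosome 18, 34859823 to 34864984), rose from 7.25 ± 0.204 to 50.8 ± 3.26 FPKM (log2 fold change 2.71, SE 0.0614, limma adjusted p = 2.30e-08), and Egr3 from 3.55 ± 0.270 to 15.8 ± 0.399 FPKM. Fosl2 and Myc of the same list, named after their values were seen, fell by 1.73 and 1.76 on the log2 scale.

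Inflammatory genes moved in both directions. Of 22 tested cytokine and mediator genes, 14 rose and 7 fell, also when adjusted over the list alone, and the list missed the threshold (median 0.48, limma camera adjusted p = 0.0538). It lay close to it: the camera adjusted p was 0.0389 without RANKL replicate 2 and 0.0451 without etelcalcetide replicate 1 (leave-one-out range 0.0389 to 0.0623). The camera adjusted p was also 0.0460 with upper-quartile scaling, 0.0223 with no filter, 0.0482 with a pseudocount of 1 FPKM and 0.0477 with the replicate block. Nlrp3, the sensor of an inflammasome, rose from 11.6 ± 0.713 to 32.5 ± 0.754 FPKM, while Nos2, inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), fell from 9.56 ± 1.65 to 1.07 ± 0.0304 FPKM. Of 24 genes of NF-kB signalling, 18 rose and 2 fell, and 18 rose and 3 fell adjusted over the list alone (median 0.46, limma camera adjusted p = 2.21e-05, adjusted p = 0.163 with an estimated correlation). Cd40, a co-stimulatory receptor, rose from 1.31 ± 0.323 to 9.55 ± 0.479 FPKM, Icam1, an adhesion molecule with 11.7% of its exon length in an overlapping gene, from 21.2 ± 0.775 to 69.5 ± 2.79 FPKM, and Nfkbia, the inhibitor of NF-kB, from 162 ± 11.2 to 289 ± 4.37 FPKM.

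Interferon-response genes rose almost without exception. Of 32 tested, 31 rose and 0 fell, also when adjusted over the list alone, and the median log2 fold change was 1.28 (limma camera adjusted p = 6.98e-15, adjusted p = 0.137 with an estimated correlation). Ifi47, named after its value was seen, did not pass (log2 fold change 0.37). Besides Irf7 (chromosome 7, 141262706 to 141266481), Oas3, an antiviral 2'-5'-oligoadenylate synthetase, rose from 8.46 ± 0.712 to 29.1 ± 1.31 FPKM and Parp14 from 2.09 ± 0.196 to 9.0 ± 0.302 FPKM. Genes of antigen presentation followed, with 17 of 21 higher and 3 lower, also when adjusted over the list alone (median 1.13, limma camera adjusted p = 6.16e-07, adjusted p = 0.137 with an estimated correlation). H2-K1, a class I heavy chain (chromosome 17, 33996017 to 34000347), rose from 35.2 ± 1.61 to 106 ± 1.63 FPKM and Tap1, a peptide transporter, from 3.18 ± 0.203 to 9.69 ± 0.231 FPKM. The 3 members that fell, H2-Aa, H2-Eb1 and H2-Ab1, named after their values were seen, encode class II chains, with log2 fold changes of -2.43, -1.73 and -0.59. Class I and class II genes are families of close copies whose reads the counting could split, so their single values are uncertain.

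**Figure D2:**
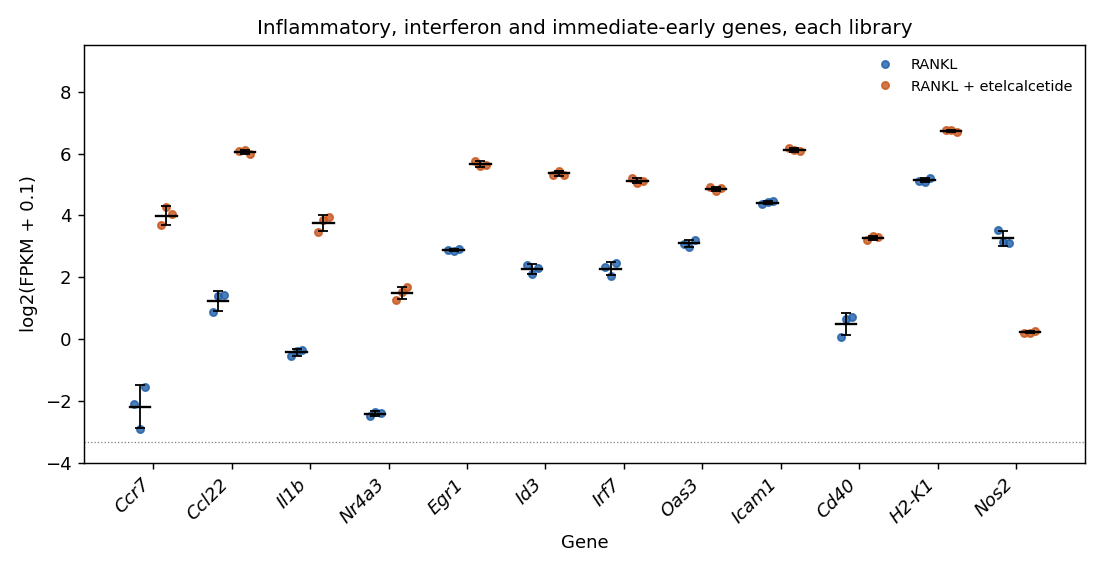
Inflammatory, interferon, immediate-early and antigen presentation genes, with log2(FPKM + 0.1) on the vertical axis. Points are libraries (blue, RANKL; orange, RANKL plus etelcalcetide), black bars are the mean and SD of the 3 log values, and the dotted line marks 0 FPKM; Nos2 is the gene whose treated points lie below the RANKL points.

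Macrophage markers shifted in a mixed way. Of 23 tested, 13 rose and 5 fell, also when adjusted over the list alone (median 0.28, limma camera adjusted p = 0.0177, adjusted p = 0.443 with an estimated correlation). Adgre1, which encodes the macrophage antigen F4/80, rose from 23.4 ± 1.34 to 70.0 ± 3.10 FPKM, and Fcgr3, an Fc receptor, from 3.62 ± 0.128 to 17.9 ± 1.91 FPKM. Lyz1, a lysozyme with a close copy in Lyz2, fell from 168 ± 14.9 to 50.4 ± 5.78 FPKM. Of 9 dendritic cell markers only 3 were high enough to test, of which Ccr7 and Zbtb46 rose, also when adjusted over the list alone. Zbtb46, a factor of classical dendritic cells, went from 0.594 ± 0.0766 to 2.15 ± 0.177 FPKM, and Itgax stood at 8.29 ± 1.59 and 8.0 ± 0.569 FPKM (limma adjusted p = 0.516, and 0.0293 without RANKL replicate 1). No marker of lymphocytes, of neutrophils and mast cells, of epithelium and endothelium or of erythroid cells was high enough to test. Of the fibroblast and osteoblast markers 1 was tested: Alpl, an alkaline phosphatase, fell from 1.13 ± 0.172 to 0.761 ± 0.0836 FPKM (limma adjusted p = 0.0185, and lost without RANKL replicate 3 at 0.0584 and without etelcalcetide replicate 3 at 0.0632).

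Genes of calcium signalling, the pathway downstream of calcium-sensing receptors, did not pass as a list. Of 36 tested, 11 rose and 9 fell, also when adjusted over the list alone, with a median of -0.02, a mean of 0.03 and an upward test direction (limma camera adjusted p = 0.756). Stim1, the calcium sensor of the endoplasmic reticulum, rose from 4.02 ± 0.172 to 6.84 ± 0.279 FPKM, and Nfatc2 rose from 4.97 ± 0.115 to 8.38 ± 0.384 FPKM, in contrast to Nfatc1.

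Cell cycle genes fell by small amounts. Of 38 S phase genes, 1 rose and 31 fell, and 1 rose and 33 fell adjusted over the list alone (median -0.36, limma camera adjusted p = 6.16e-07, adjusted p = 0.495 with an estimated correlation). Pcna, the sliding clamp of DNA replication (chromosome 2, 132249162 to 132253314), fell from 196 ± 3.80 to 116 ± 6.10 FPKM and Mcm6, a helicase subunit, from 91.7 ± 2.48 to 60.6 ± 2.64 FPKM. Of 40 G2 and M phase genes, 1 rose and 27 fell, and 1 rose and 29 fell adjusted over the list alone (median -0.29, limma camera adjusted p = 2.21e-05, adjusted p = 0.509 with an estimated correlation). Ccnb1, cyclin B1, fell from 48.1 ± 1.18 to 38.1 ± 1.83 FPKM. Of the 75 histone symbols listed, which mix older and newer names, 22 were in the annotation. Of the 8 tested, 2 rose and 2 fell, also when adjusted over the list alone (limma camera adjusted p = 0.413). Of 28 genes of the p53 response and apoptosis, 10 rose and 10 fell, also when adjusted over the list alone (limma camera adjusted p = 0.895). Zmat3, a p53-induced RNA-binding protein, fell from 6.94 ± 0.165 to 3.14 ± 0.236 FPKM and Sesn1, a stress sensor, from 37.8 ± 2.23 to 22.9 ± 1.33 FPKM. Fas, a death receptor, rose from 1.47 ± 0.300 to 4.89 ± 0.467 FPKM.

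Stress and biosynthesis lists leaned lower. For cholesterol synthesis, 1 of 24 genes rose and 14 fell, also when adjusted over the list alone (median -0.36, limma camera adjusted p = 0.00105, adjusted p = 0.509 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 18.1 ± 1.43 to 11 ± 0.531 FPKM. Among heat shock genes, 1 of 14 rose and 9 fell, with 1 and 10 adjusted over the list alone (median -0.41, limma camera adjusted p = 0.00931, adjusted p = 0.509 with an estimated correlation). Hspd1, a mitochondrial chaperonin, fell from 344 ± 23 to 214 ± 17 FPKM. For ATF4 targets of the amino acid response, 3 of 27 rose and 16 fell, with 3 and 17 adjusted over the list alone (median -0.28, limma camera adjusted p = 0.00621, adjusted p = 0.545 with an estimated correlation). Psat1, a serine synthesis enzyme of that list, fell from 151 ± 4.14 to 113 ± 9.36 FPKM. The unfolded protein response had 3 of 20 higher and 11 lower, also when adjusted over the list alone (median -0.23, limma camera adjusted p = 0.0196, adjusted p = 0.610 with an estimated correlation). Edem1, of endoplasmic reticulum quality control, fell from 59.9 ± 2.93 to 30.9 ± 1.72 FPKM.

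Ribosomal protein genes shifted little: 1 of 75 rose and 23 fell, with 1 and 22 adjusted over the list alone (median -0.10, limma camera adjusted p = 0.00674, adjusted p = 0.662 with an estimated correlation). That call was lost with library totals alone (median -0.02, limma camera adjusted p = 0.0828) and without RANKL replicate 3 (adjusted p = 0.0503; leave-one-out range 0.00016 to 0.0503), and these genes have many pseudogene copies. Nuclear genes of oxidative phosphorylation (4 of 57 higher, 11 lower, and 4 and 8 adjusted over the list alone) and the 13 mitochondrially encoded genes (0 higher, 4 lower, also when adjusted over the list alone) did not pass, at limma camera adjusted p = 0.292 and 0.0871. The mitochondrially encoded list passed without RANKL replicate 3 (limma camera adjusted p = 0.0224), without etelcalcetide replicate 1 (0.0451), with library totals alone (0.0495) and with the labelled day (0.0471), in a leave-one-out range of 0.0224 to 0.187. Glycolysis and hypoxia genes (8 of 35 higher, 8 lower, and 6 and 8 adjusted over the list alone), lipid efflux and storage genes (6 of 21 higher, 9 lower, and 6 and 10 adjusted over the list alone) and iron and zinc genes (6 of 16 higher, 4 lower, also when adjusted over the list alone) did not pass either, at limma camera adjusted p = 0.917, 0.413 and 0.853. Apoe, the lipid carrier, nonetheless fell from 7.51 ± 1.13 to 2.07 ± 0.206 FPKM, and Cpt1a, which admits fatty acids to mitochondria, rose from 5.49 ± 0.149 to 15.3 ± 1.83 FPKM. The NRF2 antioxidant list had 13 of 26 higher and 5 lower, and 14 and 5 adjusted over the list alone (limma camera adjusted p = 0.0538). It passed without RANKL replicate 3 (limma camera adjusted p = 0.0371) and without etelcalcetide replicate 1 or 3 (0.0426 and 0.0468), with library totals alone (0.0360), no filter (0.0250) and the labelled day (0.0484), in a leave-one-out range of 0.0371 to 0.0990. Me1, malic enzyme, fell from 31.0 ± 9.20 to 4.67 ± 0.33 FPKM. Pgd, of the pentose phosphate pathway, rose from 67.5 ± 2.48 to 102 ± 4.06 FPKM.

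**Figure D3:**
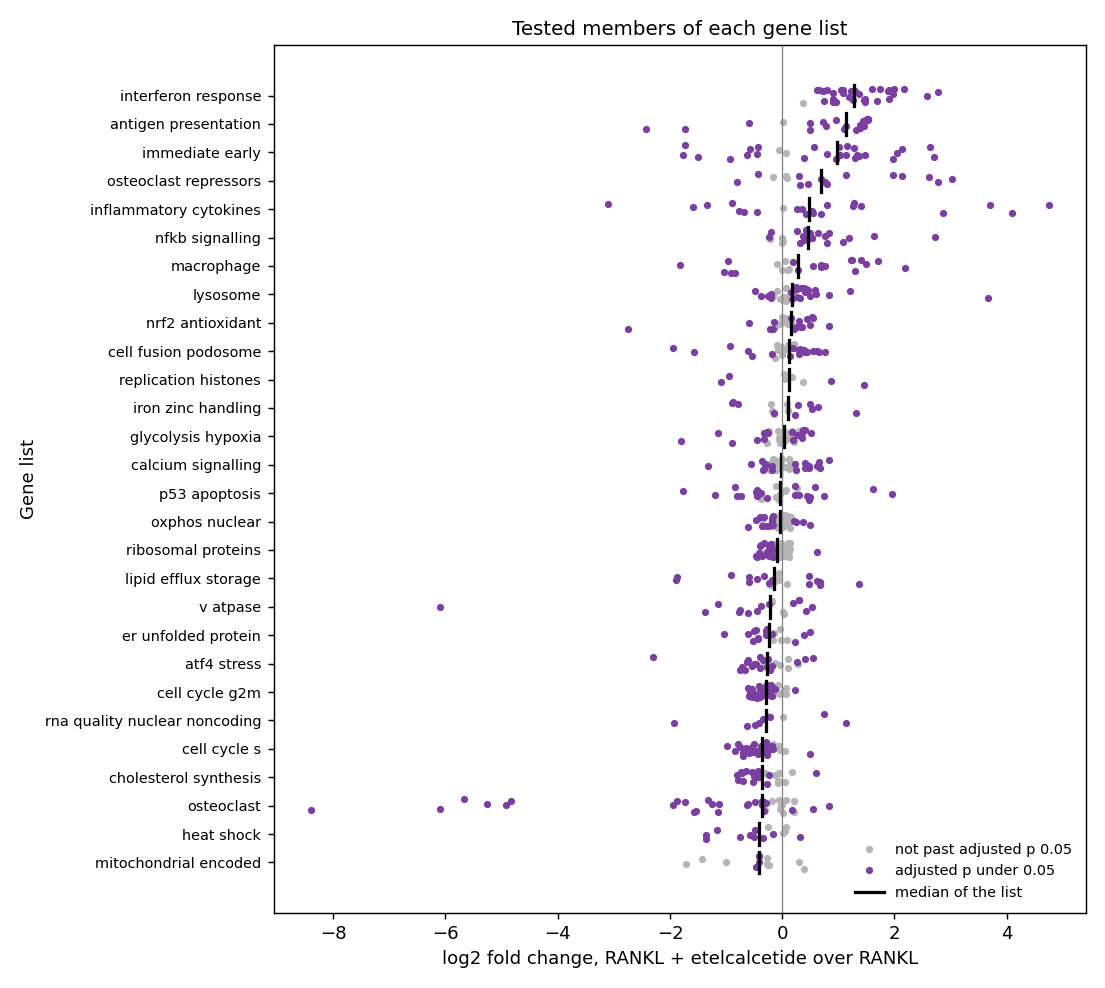
Log2 fold change (RANKL plus etelcalcetide over RANKL, horizontal axis) of every tested member of the 28 lists with at least 5 tested genes. Purple points passed and grey points did not pass the limma test. Black bars are list medians, which were 1.28 for interferon-response genes and -0.36 for osteoclast genes. The lowest medians were those of mitochondrially encoded and heat shock genes, both -0.41.

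Signs of library quality were compared in the same way, by a two-sided exact permutation test whose smallest p with 3 against 3 is 0.1, so none could pass 0.05. Genes detected numbered 16957 ± 107 in the RANKL group and 17339 ± 138 in the treated group (exact p = 0.1). Mitochondrially encoded genes took 3.72 ± 0.498% and 3.17 ± 0.190% of reads (exact p = 0.2). The nuclear RNA Malat1 took 0.0538 ± 0.0133% and 0.123 ± 0.0197% (exact p = 0.1), and it rose from 77.0 ± 19.0 to 177 ± 28.2 FPKM in the gene test. The list of nuclear noncoding RNAs had 2 of 10 higher and 6 lower, also when adjusted over the list alone (limma camera adjusted p = 0.108). Snhg5 and Gas5, host genes of small nucleolar RNAs, fell from 10.1 ± 0.789 to 6.88 ± 0.261 FPKM and from 29.7 ± 2.82 to 22.4 ± 0.376 FPKM. Annotated rRNA genes took 1.27 ± 0.295% and 1.17 ± 1.19% of reads (exact p = 1.0), from 0.323% in etelcalcetide replicate 3 to 2.53% in etelcalcetide replicate 2.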

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

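The settings with other pseudocounts, the FPKM minimum alone and an FPKM minimum of 1 were chosen after the data were seen. Across scalings, filters, pseudocounts, voom, the labelled day and protein-coding genes alone, between 5355 and 6133 genes changed, against 5894, and leaving out each library gave 4797 to 6168. A fold change of at least 2 left 781 genes (456 higher, 325 lower), and limma's treat against 1.2-fold left 2294 (1214 higher, 1080 lower), both by construction. No called result reversed among 127 genes over 13 settings and 28 lists over 17; 1632 gene values kept their side of the threshold, 18 lost it (Hist1h1b, Hist1h1e, mt-Nd1 and Alpl) and 1 gained it (Itgax). The planned DESeq2 and edgeR fits were not run; voom on the recovered reads (6133 genes) was the one fit of read counts.

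No clear effect shared by same-numbered libraries was seen. Their deviations from the group means correlated at 0.07, -0.02 and -0.03 for replicates 1, 2 and 3. RANKL replicate 3 correlated best with etelcalcetide replicate 2 (0.11). These correlations were not tested and cannot show whether the numbers mark shared cultures. With the replicate block 5709 genes changed (2777 higher, 2932 lower), and the inflammatory list passed camera (adjusted p = 0.0477).

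With an estimated correlation, each of the 16 lists that passed limma's camera lost its call, with adjusted p values of 0.137 (interferon, antigen presentation), 0.163 (NF-kB, osteoclast repressors), 0.443 (macrophage), 0.495 (S phase), 0.509 (osteoclast, immediate-early, cholesterol, heat shock, G2 and M phase), 0.545 (lysosome, ATF4), 0.610 (V-ATPase, unfolded protein response) and 0.662 (ribosomal proteins). The estimate comes from 6 libraries. Among these lists it ran from 0.0146 (osteoclast repressors) to 0.443 (unfolded protein response), against the preset 0.01. Calls were lost even where the estimate lay near the preset, so a lost call alone does not show that the members of a list vary together. Under fry, which tests a list on its own and not against the other genes, lists that failed camera passed: inflammatory (0.000761), NRF2 (0.0134), nuclear noncoding RNA (0.0154), histones (0.0219), calcium (0.0386) and lipid (0.0386), while ribosomal proteins did not (0.0553). Most tested genes had changed, so a pass under fry is easily reached and does not show that a list stands out. It does not show that members move one way either, because the calcium and histone lists passed with members changed in both directions. The inflammatory list passed camera with upper-quartile scaling (0.0460), no filter (0.0223) and a pseudocount of 1 (0.0482). The NRF2 list passed with library totals (0.0360), no filter (0.0250) and the labelled day (0.0484). The mitochondrially encoded list passed with library totals (0.0495) and the labelled day (0.0471), and ribosomal proteins failed with library totals (0.0828). Leaving out each library gave camera adjusted p ranges of 0.0389 to 0.0623 (inflammatory), 0.0103 to 0.155 (V-ATPase), 0.0224 to 0.187 (mitochondrially encoded), 0.0371 to 0.0990 (NRF2) and 0.00016 to 0.0503 (ribosomal proteins). The cause was not tested. Depth limits Casr and Calcr, whose values lie at or near 0 reads.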

Other observations

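The lists of clock, integrin, chemoattractant receptor and Toll-like receptor genes, and every test here except that of the sample splits, were chosen after the results were seen. Among circadian clock genes, 5 of 14 tested rose and 8 fell (limma camera adjusted p = 0.148 over these 4 lists, and adjusted p = 0.263 with an estimated correlation). Cry1, a repressor of the clock, fell from 46.6 ± 1.95 to 9.59 ± 0.433 FPKM (n = 3 per group, log2 fold change -2.35, limma adjusted p = 4.47e-08). Arntl and Nr1d1 fell by 1.19 and 0.92 on the log2 scale, while Per1 and Nfil3 rose by 1.10 and 1.14. Both groups carry the same labelled days, and the hour of harvest is not given in the sources used here.

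Receptors for migration and adhesion also moved in both directions. Of 10 tested chemoattractant receptors 4 rose and 3 fell (limma camera adjusted p = 0.389). Ccr1, a receptor for Ccl3 and related chemokines, fell from 9.26 ± 1.24 to 0.124 ± 0.0516 FPKM, while Ccr7 rose, Ccrl2 rose from 0.655 ± 0.236 to 8.15 ± 0.590 FPKM and C5ar1, the complement C5a receptor, from 10.7 ± 1.23 to 37.6 ± 3.64 FPKM. Of 12 tested integrin genes 6 rose and 2 fell (limma camera adjusted p = 0.148). Itgal, the alpha chain of LFA-1, rose from 2.32 ± 0.125 to 26.5 ± 1.36 FPKM, and Itga4 fell from 170 ± 33.8 to 86.6 ± 4.55 FPKM. Some changed genes switched close to on or off: 6 had a mean under 0.1 FPKM with RANKL and at least 1 FPKM with etelcalcetide, and 28 the opposite. Gprc6a, a relative of Casr that senses amino acids and cations, was listed at 0 FPKM in all 6 libraries, like Casr.

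The count of changed genes was set against other splits of the 6 libraries. The real split gave 5894 changed genes, and only 1 of the 10 splits, the real one, gave that many; the highest of the others gave 0 by limma, with at most 202 genes at an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05. Every other split mixed RANKL and treated libraries on each side, so the difference between the groups added to the spread within sides. Low counts in those splits were therefore built in, and they give no chance level for the 5894 genes.

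Of 37 tested osteoclast genes 23 fell and 3 rose, and of 32 interferon-response genes 31 rose, with limma camera calls lost at adjusted p = 0.509 and 0.137 with an estimated correlation. Library scaling was set against this pattern: over 4 scalings the osteoclast median closest to 0 was -0.284 and the lowest interferon median 1.27, so scaling is not the whole cause. RNA of lymphocytes, granulocytes, fibroblasts, osteoblasts, epithelium, endothelium or erythroid cells is argued against by their markers, of which the highest in the treated libraries, Alpl, reached 0.761 FPKM. Suppose the treated cultures only held fewer osteoclasts, these did not divide and each cell type kept a fixed profile. The RNA share of dividing cells would then have to rise at least as much as the deposited mean FPKM of Ccl22 (29.1-fold, 4.86 on the log2 scale). The S phase list instead had a median of -0.355 with an SD of 0.285 between members. Neither condition was measured and Ccl22 was among the genes that rose most, so only that narrow case is argued against. A shift in cells that carry osteoclast genes and still divide may account for part of the pattern; that, an effect of etelcalcetide within cells and a difference between the cell stocks of the groups stay open and untested, with Casr not detected at this depth and no library without RANKL analysed here.

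The higher inflammatory genes raise the question of a Toll-like receptor ligand such as endotoxin in the peptide preparation. Of 15 tested genes of that response 80% rose (12 genes; limma camera adjusted p = 0.00013 over the same 4 lists, and adjusted p = 0.0454 with an estimated correlation). This decides nothing, because the list was chosen after inflammatory genes were seen to rise and 12 of the 15 also stand in the lists fixed earlier. Nos2 and Ccl3, which such ligands also raise, fell by 3.11 and 1.58 on the log2 scale, and Il6 and Marco were listed at 0 FPKM in all 6 libraries. A ligand and an effect of etelcalcetide itself cannot be told apart here, because a single late time point does not show an early response, and the labels do not say what the cells without etelcalcetide received in its place.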
